A study of Mus musculus with 13 samples.

How the data were processed

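Gene expression was measured by RNA sequencing in mouse 129SV cells. Embryonic stem cells (ESCs) come from the inner cell mass of the blastocyst, and trophoblast stem cells (TSCs) from the lineage that forms the placenta. Polyadenylated RNA was selected with poly-T beads and made into libraries with a NEBNext kit, per the labels' protocols. Reads were aligned with HISAT2 2.0.5 to mm10 and counted per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The deposited counts are whole numbers of reads per gene and are not normalized. The authors also deposited FPKM values, which are scaled for gene length and library size. Strand handling, treatment of reads that match several places, the annotation and the program behind the FPKM values are not given in the sources used here. Reads of near-identical genes can therefore be split or lost, and a gene cannot be told apart from an antisense partner that overlaps it.

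Both tables held 55487 genes, of which 55227 had a name in GENCODE mouse release M21. In 2 row names the submitters had appended a symbol. No count in any library was found for 16681 genes. Among 7864 genes with at least 500 counts in every library, the ratio of count to FPKM departed by over 1.5 times in some library for 117. Groups were taken from the sample labels alone. All replicate pairs differed by more than sampling noise, with a median chi-square over its expectation of 5.48 to 5.83 in wild-type groups, 24.8 to 38.0 in induced cells and 78.1 to 174 in heterozygous cells.

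Genes with at least 10 counts per median library in at least 3 libraries were tested, 23386 in all. Library sizes were scaled by TMM. One edgeR 4.0.16 quasi-likelihood model with robust estimation in R 4.3.3 held all 13 libraries with 1 term per group and no other covariate. Adjusted p-values of genes are Benjamini-Hochberg values over all genes tested, and genes under 0.05 are called. Levels are in CPM, counts scaled to library size, with SD, and log2 fold changes with SE. Gene lists were tested against all other genes with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and again with an estimated correlation. Each comparison tested the replication-origin list and 32 others. Adjusted p-values of lists are Benjamini-Hochberg values over these lists, and lists under 0.05 are called. For each list the number of called members is also given with p adjusted over the list alone. The lists described below cover pluripotency, trophoblast stem cell, giant cell, epithelial, primitive endoderm, formative epiblast, fibroblast, germline, interferon, replication-origin, DNA methylation, H3K9 silencing, WNT, FGF and ERK, glycolysis, histone, 2-cell-like and sex-linked genes. The lineage position projected log2 CPM with a prior count of 2 on the axis from mean wild-type ESC to mean wild-type TSC, over genes called with at least a 2-fold change.

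Named genes followed a rule fixed with the lists, the design and most alternatives before the data were examined. It took Rif1, Hmgn3, Pou5f1, Nanog, Cdx2, Eomes and Elf5 whatever their result. It took the 5 highest and 5 lowest called protein-coding genes with at least 10 CPM in the higher group and no overlap between the groups' libraries. From each described list it took up to 4 members with the smallest adjusted p. For the library labelled homozygous it took the 3 highest and 3 lowest. Values per library of sex-linked and fibroblast genes were added after they were seen.

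A group without a count was set to a floor of 3 counts over the group, which gives a lower bound for a fold. A group with 1 to 3 counts gave a ratio with a 95% counting interval. Floors and intervals cover counting error only. Coordinates are on mm10. Alternatives were other size factors, DESeq2 1.42.0, no filter and a filter of 50 counts, limma on FPKM with pseudocounts of 1 and 0.1, fits of the compared groups only, with and without a replicate block, and each replicate left out. A correction for exon length and GC content, and a fit without heterozygous replicate 1 and the library labelled homozygous, were chosen after seeing the data. The model was tested on simulated counts with 200 changed genes among 23386. Of genes changed 2-fold it recovered 11.9%, 11.9%, 4.55%, 5.97% and 0% for the comparisons in the order that follows. Of genes changed 4-fold it recovered 60.6% for wild-type TSCs against ESCs, 65.2% for heterozygous against wild-type ESCs, 47.0% for induced cells against heterozygous ESCs, 56.1% for induced cells against wild-type TSCs and 34.8% for the difference of the 2 TSC-ESC comparisons. Unchanged genes were called at most 3 times in any of these. The simulation gave all groups the same spread, unlike the real ones. It therefore cannot show how often unchanged genes are called in these data.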

Results

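The series held 13 libraries. Wild-type ESCs, wild-type TSCs and ESCs heterozygous for a Rif1 knockout had 3 libraries each by their labels, as did induced TSCs (iTSCs) labelled as Rif1 knockouts, and 1 library was labelled as homozygous Rif1-knockout ESCs. Total counts were 69216474, 73298465 and 79474410 in wild-type ESCs, 70972999, 71735457 and 73416708 in wild-type TSCs and 80653709, 68324743 and 72336178 in heterozygous ESCs. They were 63622924 in the library labelled homozygous and 68757551, 66259195 and 67318917 in iTSCs. The titles number wild-type and Rif1 libraries as separate series, so genotype and series coincide in any comparison between them. The labels do not say whether replicates were separate cultures. P-values measure only the spread between these samples, as 1 spread per gene shared by all groups. Replicates differed far more in heterozygous ESCs than in wild-type groups.

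Rif1, a replication-timing and DNA repair factor at chromosome 2, 52072832 to 52122383, was measured first as a check of the labels. It stood at 528, 525 and 530 CPM in wild-type ESCs and at 65.6, 67.3 and 65.5 CPM in wild-type TSCs. Heterozygous ESC replicates 1, 2 and 3 had 41.6, 333 and 118 CPM. The library labelled homozygous had 1240 CPM from 84478 counts, the highest Rif1 level of the 13 libraries, which goes against its label. The iTSCs labelled as Rif1 knockouts had 198, 142 and 137 CPM, above wild-type TSCs, so they showed no loss of Rif1 RNA. Their excess over wild-type TSCs did not pass the test given below. Counts span the whole gene, and the part of Rif1 altered by the knockout is not given in the sources used here. RNA levels alone therefore cannot settle the genotype. Hmgn3, a nucleosome-binding protein gene at chromosome 9, 83109948 to 83146685, had 0.988 ± 0.319 CPM (SD, n = 3) in wild-type ESCs, 4.46 ± 0.147 in heterozygous ESCs, 3.86 in the library labelled homozygous, 7.19 ± 3.04 in iTSCs and 11.9 ± 1.22 in wild-type TSCs.

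**Figure D1:**
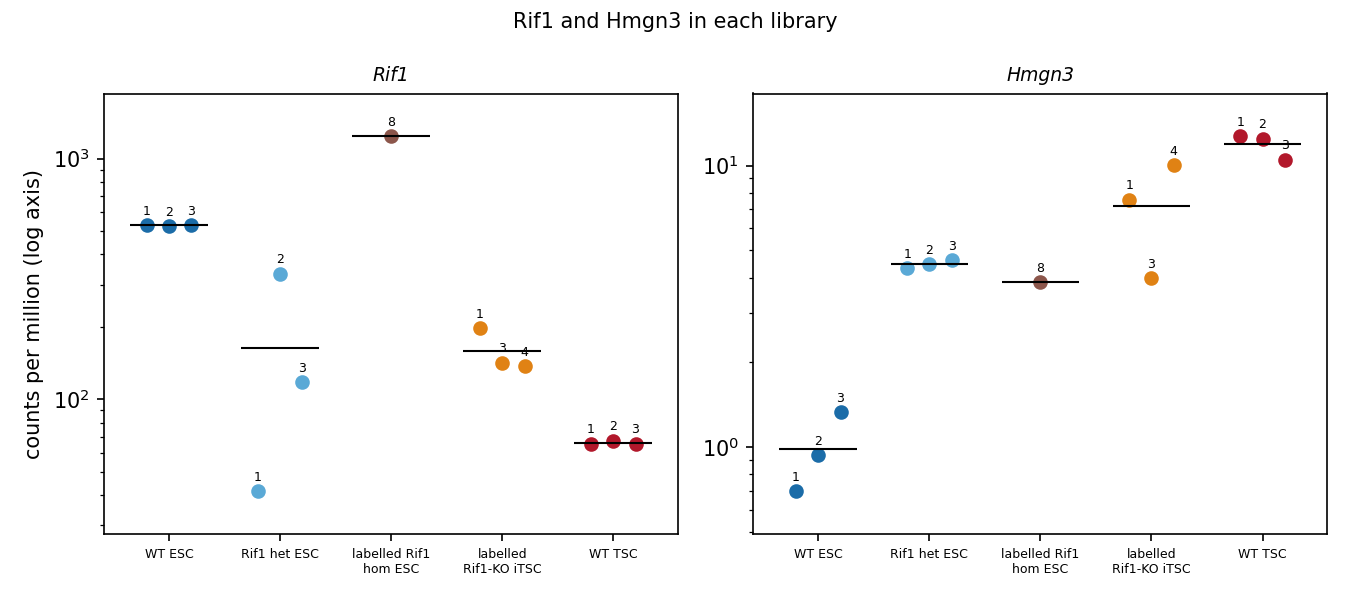
Rif1 and Hmgn3 in each library, in CPM on a log axis; points are libraries with their replicate number and lines are group means. The library labelled homozygous has 1240 CPM of Rif1, above the 525 to 530 CPM of wild-type ESCs.

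Wild-type TSCs were compared with wild-type ESCs to define the difference between the lineages. The pluripotency regulators Pou5f1 and Nanog fell, with log2 fold changes of -11.27 ± 0.41 (SE) and -11.16 ± 0.52, from 1785 and 717 CPM. Cdx2 and Eomes, regulators of trophoblast fate, rose by 5.20 ± 0.31 and 3.01 ± 0.22. Elf5, another trophoblast regulator, had 3 counts in wild-type ESCs against 137 ± 2.79 CPM in TSCs, a ratio of 9251 with an interval of 3166 to 44859. Rif1 fell by 3.00 ± 0.54 (adjusted p = 0.00062) and Hmgn3 rose by 3.58 ± 0.36 (adjusted p = 7.6e-06). Tdgf1, a co-receptor of Nodal, had no count in TSCs and was at least 49821-fold lower there. Fam25c, Myh13 and Kirrel2 were at least 6613-, 3327- and 1878-fold lower, and Trh, which encodes thyrotropin-releasing hormone, fell by 13.68 ± 1.59. Mmp3, Lyz2, Cxcl1, Ifit1 and Dkk2 had no count in ESCs and were at least 25386-, 11508-, 9248-, 6884- and 5679-fold higher in TSCs.

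Of 25 pluripotency genes 23 fell, also with p adjusted over the list alone, among them Fgf4 (-9.38 ± 0.25), Dppa5a (-7.76 ± 0.25) and Fbxo15 (-6.64 ± 0.22); the list moved with adjusted p = 4.2e-40. Of 24 TSC genes 19 rose (19 adjusted over the list alone), including Msx2 (3.30 ± 0.17), Id2 (5.15 ± 0.26) and the FGF receptor Fgfr2 (5.97 ± 0.33), with adjusted p = 6.4e-15. All 15 giant cell genes rose (15 adjusted over the list alone), such as the protease Mmp9 (8.06 ± 0.46), with adjusted p = 3.7e-17. Prl2c2 of this list has near-identical copies, which makes its value uncertain. Epithelial genes rose in 16 of 19 cases (17 adjusted over the list alone), with the keratin Krt8 at 6.33 ± 0.43, Cldn3 at 4.70 ± 0.33, Grhl2 at 4.17 ± 0.28 and the cadherin Cdh3 at 2.56 ± 0.22. Replication-origin genes fell in 17 of 18 cases (17 adjusted over the list alone), including the helicase subunits Mcm3 (-2.41 ± 0.12), Mcm6 (-2.27 ± 0.15) and Mcm2 (-2.02 ± 0.12) and Gins1 (-2.35 ± 0.15). Adjusted p of the epithelial and replication-origin lists was 9.8e-10 and 3.5e-12. All 5 lists also passed with an estimated correlation.

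Fibroblast genes rose in 21 of 22 cases (21 adjusted over the list alone), including Pdgfrb (4.45 ± 0.33), Twist1 (4.32 ± 0.52), Dcn (12.36 ± 2.07) and the collagen Col5a1 (5.49 ± 0.98). Their summed level was 13071 to 13114 CPM in wild-type TSCs against 1877 to 1942 CPM in wild-type ESCs. The list had adjusted p = 0.00021, and adjusted p = 0.50 with an estimated correlation. Interferon-response genes rose in 19 of 20 cases (19 adjusted over the list alone), including Bst2 (5.12 ± 0.29), Irf7 (9.77 ± 0.72) and Oasl2 (11.21 ± 0.82), with Cxcl10 at least 2670-fold higher; adjusted p = 3.5e-12, and adjusted p = 0.065 with an estimated correlation. Genes of the 2-cell-like state fell in 29 of 33 cases and rose in 1 (30 and 1 adjusted over the list alone), with adjusted p = 9.7e-16, and adjusted p = 0.11 with an estimated correlation; the Zscan4 copies that lead this list are near-identical and uncertain. The Y-linked genes Eif2s3y and Ddx3y rose by 9.37 ± 0.87 and 8.06 ± 0.89. Wild-type ESC replicates 1, 2 and 3 had 0, 3 and 13 counts of Eif2s3y. Sex or cell line therefore cannot be told apart from lineage in this comparison. In all, edgeR called 13166 of 23386 genes, 6606 higher and 6560 lower, 10396 of them at least 2-fold.

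**Figure D2:**
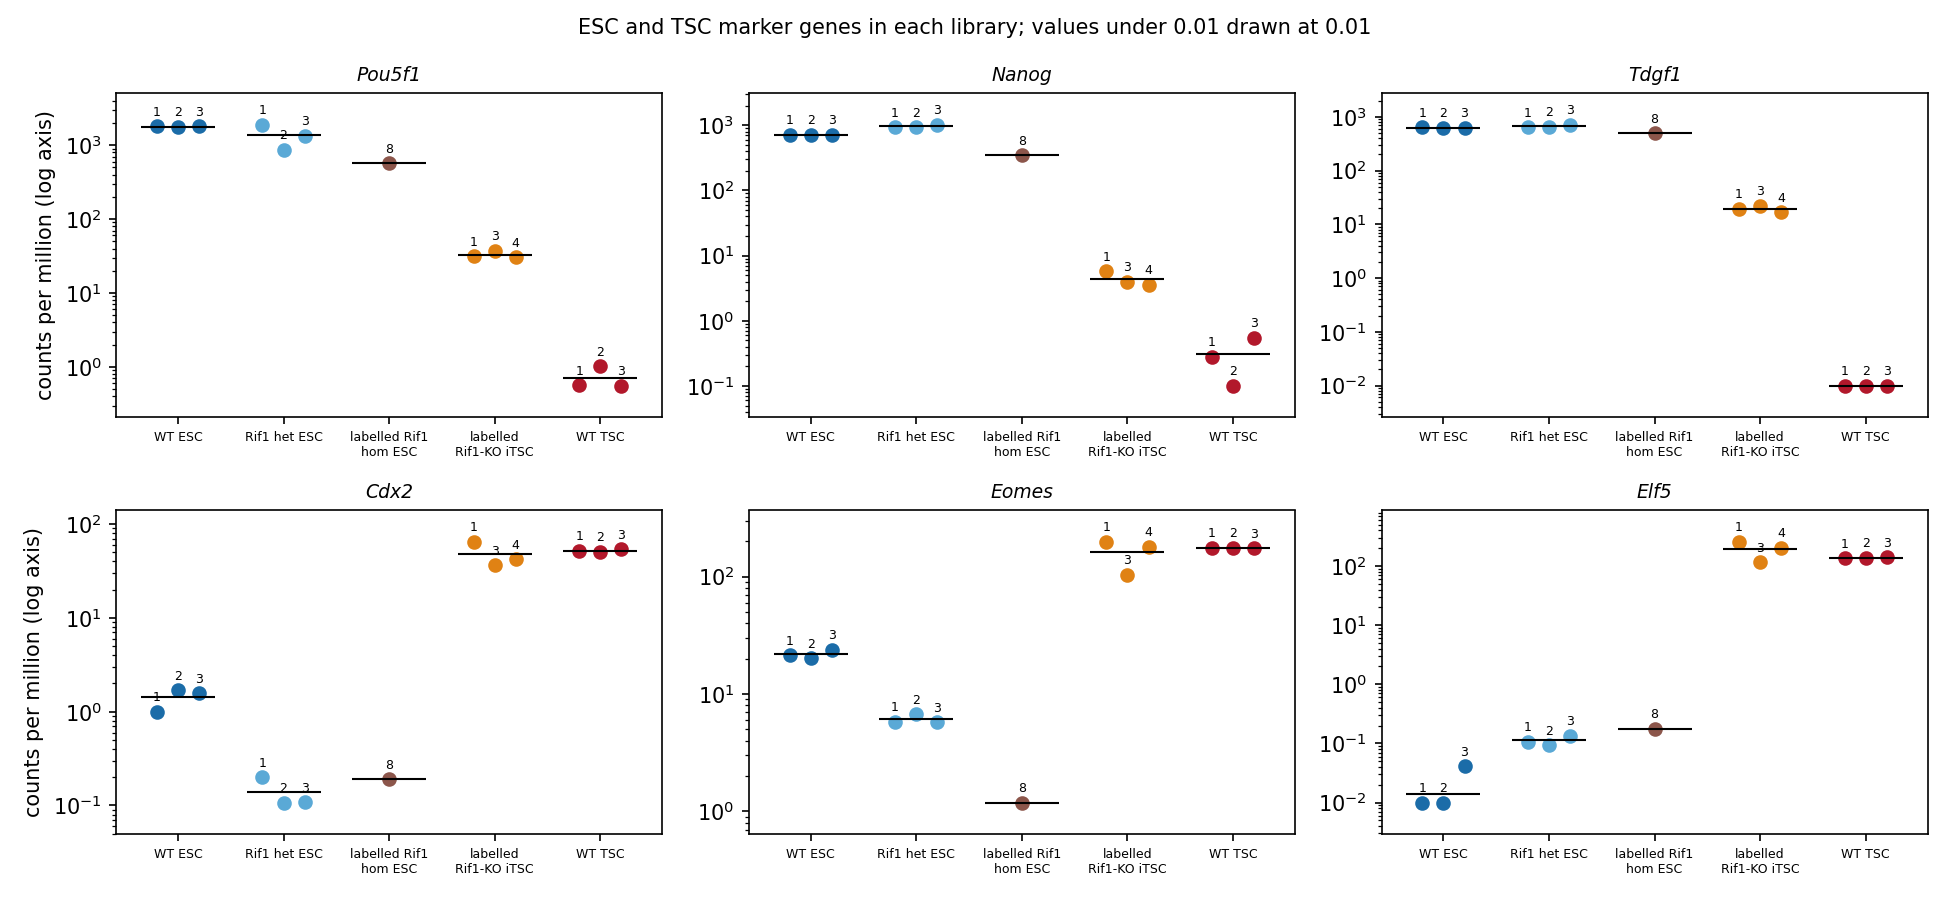
ESC genes Pou5f1, Nanog and Tdgf1 and TSC genes Cdx2, Eomes and Elf5 in each library, in CPM on a log axis; points are libraries with their replicate number, lines are group means and values under 0.01 are drawn at 0.01. iTSC means are 33.1 CPM for Pou5f1 and 47.7 CPM for Cdx2.

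iTSCs were compared with heterozygous ESCs, both of the Rif1 series. As iTSCs showed no loss of Rif1 RNA and the altered part of the gene is unknown, their knockout cannot be checked here. No direction in their comparisons can therefore be read as that of a Rif1 knockout. Pou5f1 and Nanog fell, with log2 fold changes of -5.37 ± 0.32 and -7.75 ± 0.44, to 33.1 ± 3.58 and 4.46 ± 1.19 CPM (SD, n = 3). Cdx2, Eomes and Elf5 rose by 8.41 ± 0.38, 4.72 ± 0.24 and 10.72 ± 0.49, to 47.7 ± 15.1, 161 ± 49.9 and 192 ± 71.3 CPM. Rif1 had a log2 fold change of -0.04 ± 0.50 (adjusted p = 0.95) and Hmgn3 of 0.69 ± 0.33 (adjusted p = 0.11), and neither passed the test. Without heterozygous replicate 2, which had the highest Rif1 of its group, Rif1 was higher in iTSCs by 1.00 (adjusted p = 0.034, the lowest over its 18 alternatives). Without iTSC replicate 3, Hmgn3 was higher by 0.98 (adjusted p = 0.018), and its adjusted p ranged up to 0.87 over 18 alternatives. Crxos, Fam25c, Myh13 and Spic had no count in iTSCs and were at least 7254-, 2119-, 1472- and 1027-fold lower. Stra8, a meiosis gene, had 3 counts in iTSCs, a ratio of 10049 with an interval of 3439 to 48728. Ctsj, a placental cathepsin, was at least 1205-fold higher. Prl2c2, Prl3d1 and Serpinb9f, members of families with close copies, were also without a count in heterozygous ESCs and are uncertain.

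Of 24 TSC genes 23 rose (23 adjusted over the list alone), such as Msx2 (4.13 ± 0.18) and Id2 (5.44 ± 0.27), with adjusted p = 1.3e-28. Of 25 pluripotency genes 21 fell and 2 rose, with the same counts adjusted over the list alone; the most certain falls were in Fbxo15 (-6.96 ± 0.22), Fgf4 (-6.86 ± 0.22), Dppa5a (-6.18 ± 0.24) and Tdgf1 (-5.09 ± 0.16), and the list had adjusted p = 6.4e-26. Giant cell genes rose in 13 of 15 cases and fell in 1 (13 and 1 adjusted over the list alone), with adjusted p = 1.8e-18. Epithelial genes rose in 17 of 19 cases (17 adjusted over the list alone), including Krt8 (6.08 ± 0.43), the claudins Cldn3 (5.09 ± 0.33) and Cldn4 (3.76 ± 0.23) and the laminin Lama5 (2.76 ± 0.14), with adjusted p = 1.0e-16. Replication-origin genes fell in 13 of 18 cases (14 adjusted over the list alone), including Gins1 (-1.58 ± 0.14), Mcm5 (-1.54 ± 0.17), Mcm3 (-1.25 ± 0.11) and Mcm2 (-1.10 ± 0.12), with adjusted p = 0.00023. These 5 lists also passed with an estimated correlation.

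Genes of the 2-cell-like state fell in 31 of 33 cases (31 adjusted over the list alone), with adjusted p = 1.9e-10, and adjusted p = 0.24 with an estimated correlation. Interferon-response genes rose in 15 of 20 cases (17 adjusted over the list alone), including Bst2 (3.71 ± 0.27) and Stat1 (2.89 ± 0.26), with adjusted p = 5.1e-07, and adjusted p = 0.13 with an estimated correlation. Xist, the RNA of X inactivation, rose by 6.68 ± 1.03 to 1801, 1200 and 1062 CPM in iTSCs, while Eif2s3y (-4.54 ± 0.66) and Ddx3y (-2.94 ± 0.69) fell. Xist overlaps its antisense partner Tsix, which fell by 3.45 ± 0.45, and the strand of counting is not given. As Xist and Y-linked genes differed between the groups, sex or cell line cannot be told apart from conversion in this comparison. Fibroblast genes summed to 730, 1244 and 7524 CPM in heterozygous replicates 1, 2 and 3 and to 1855, 892 and 1697 CPM in iTSCs. Of these 22 genes 2 were called lower (1 adjusted over the list alone), and the list had a median log2 fold change of -1.41, opposite in sign to its test, with adjusted p = 0.99. Without heterozygous replicate 3, 16 were called higher and 1 lower, with adjusted p = 4.6e-08. edgeR called 10831 genes, 4920 higher and 5911 lower. With the 2 groups fitted alone the count was 7106.

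This comparison and that of wild-type TSCs with wild-type ESCs shared no library, and 6927 genes were called in the same direction in both, 3171 higher and 3756 lower. Independent lists of these sizes would share 1390 and 1658. Another 702 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.566 and a Spearman correlation of 0.559. Of 5664 genes at least 2-fold higher in wild-type TSCs, 2694 (47.6%) were also called higher in iTSCs; of 4732 lower, 3001 (63.4%) were also called lower. On the axis from mean wild-type ESC at 0 to mean wild-type TSC at 1, iTSCs lay at 0.737 ± 0.0156 (SD, n = 3), heterozygous ESCs at 0.239 ± 0.0660 and the library labelled homozygous at 0.361. Heterozygous replicates 1, 2 and 3 lay at 0.205, 0.196 and 0.315. Over genes lower in TSCs alone, iTSCs reached 0.824 ± 0.0188, and over genes higher in TSCs 0.690 ± 0.0286. The higher genes include fibroblast genes, which were also high in heterozygous replicate 3 and in the library labelled homozygous. Wild-type libraries left out of the axis lay at 0.0156 to 0.0261 for ESCs and 0.986 to 0.989 for TSCs. They were replicates of the same groups that set the axis and its genes, and these groups also differed in Y-linked genes. Their places therefore do not show where other ESC or TSC lines would lie.

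**Figure D3:**
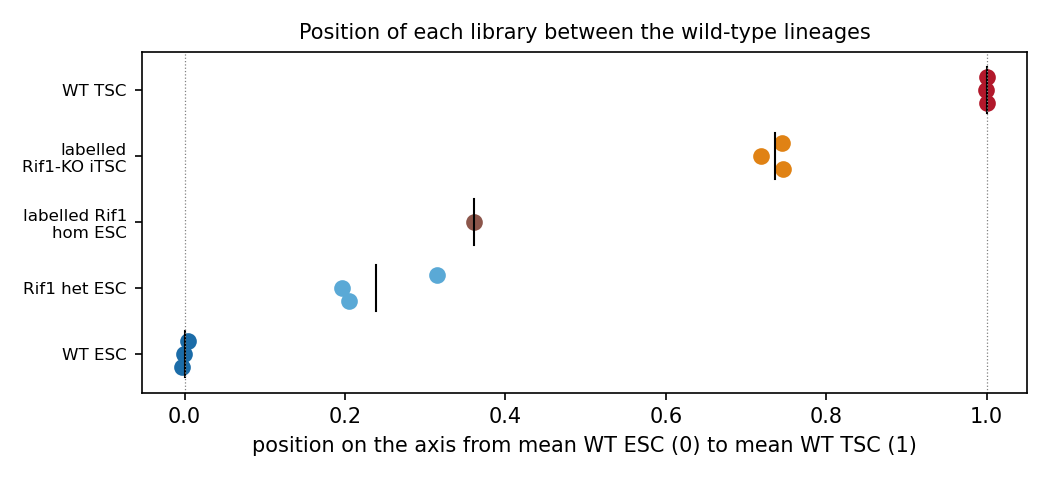
Position of each library on the axis from mean wild-type ESC (0) to mean wild-type TSC (1), over 10396 genes; points are libraries and lines group means. iTSC libraries lie between 0.719 and 0.746.

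**Figure D4:**
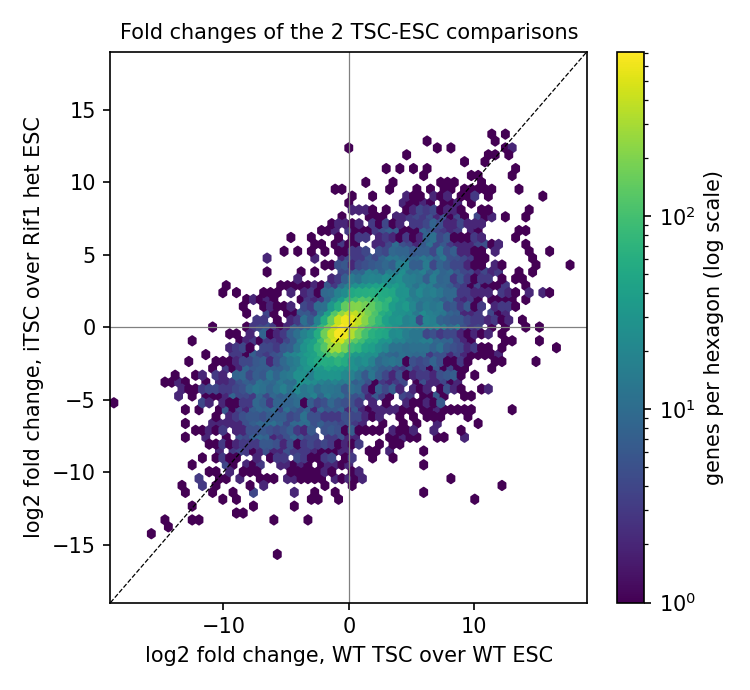
Log2 fold changes of wild-type TSCs over wild-type ESCs (horizontal) and of iTSCs over heterozygous ESCs (vertical), with the number of genes per hexagon on a log color scale and the line of equal change dashed. The Pearson correlation across genes is 0.566.

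iTSCs were then compared with wild-type TSCs. Pou5f1 and Nanog were higher in iTSCs by 5.52 ± 0.33 and 3.83 ± 0.40, at 33.1 and 4.46 CPM against 0.719 and 0.311 CPM. Tdgf1 had no count in wild-type TSCs and was at least 1546-fold higher. Cdx2 (-0.13 ± 0.26, adjusted p = 0.76), Eomes (-0.13 ± 0.20, adjusted p = 0.70) and Elf5 (0.48 ± 0.31, adjusted p = 0.27) did not pass the test. Rif1 had 1.27 ± 0.51 (adjusted p = 0.091), and 1.13 (adjusted p = 0.00046) with the 2 groups fitted alone, the lowest of a range up to 0.33 over 16 alternatives. Hmgn3 had -0.72 ± 0.33 (adjusted p = 0.13), and -0.83 (adjusted p = 0.043) with DESeq2, within a range of 0.012 to 0.32 over 16 alternatives. Bcor, a co-repressor gene on the X chromosome, rose by 4.66 ± 0.34, the channel gene Hcn2 by 4.96 ± 0.41 and Trim9 by 5.31 ± 0.82. The chemokine Ccl11 and the matrix gene Dpt had no count in iTSCs and were at least 3925- and 1840-fold lower. Saa3 (-9.41 ± 0.31), Ccl8 (-8.95 ± 1.11) and Cxcl5 (-8.87 ± 1.75) also fell.

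Pluripotency genes rose in 12 of 25 cases and fell in 2 (13 and 2 adjusted over the list alone), with Fgf4 at 2.68 ± 0.20 and Klf4 lower at -3.24 ± 0.27; adjusted p = 1.1e-10. Formative epiblast genes rose in 7 of 12 cases (8 adjusted over the list alone), including Otx2 (7.55 ± 0.62), Foxd3 (2.96 ± 0.34), Lef1 (2.39 ± 0.32) and Dnmt3b (1.38 ± 0.17), with adjusted p = 1.2e-05; Foxd3 lost its call with limma on log2(FPKM + 1) (0.62, adjusted p = 0.061). WNT targets rose in 8 of 12 cases and fell in 1 (8 and 2 adjusted over the list alone), including Cdx1 (4.22 ± 0.41), Sp5 (3.97 ± 0.57) and Tcf7 (1.69 ± 0.19), with adjusted p = 0.00065. Replication-origin genes rose in 15 of 18 cases (17 adjusted over the list alone), including Cdt1 (1.41 ± 0.15), Mcm6 (1.24 ± 0.14), Mcm3 (0.83 ± 0.11) and Mcm2 (0.82 ± 0.12), with adjusted p = 6.7e-08. These 4 lists also passed with an estimated correlation. TSC genes rose in 8 of 24 cases (10 adjusted over the list alone), including Id2 (1.52 ± 0.23), Fgfr2 (1.41 ± 0.27), Gata3 (1.76 ± 0.37) and Ets2 (1.08 ± 0.18), with adjusted p = 0.018, and adjusted p = 0.095 with an estimated correlation. If other cells gave the fibroblast RNA of the wild-type TSC libraries, other RNAs would hold a smaller share there. Part of the rise of replication-origin and TSC genes could come from that, which was not tested.

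Fibroblast genes fell in 12 of 22 cases (17 adjusted over the list alone), including Pdgfrb (-3.62 ± 0.31), Twist1 (-4.16 ± 0.52), fibronectin Fn1 (-2.14 ± 0.34) and Lum (-8.73 ± 1.62); adjusted p = 1.4e-08, and adjusted p = 0.32 with an estimated correlation. Interferon-response genes fell in 9 of 20 cases (9 adjusted over the list alone), including Ifit3 (-5.52 ± 0.82), Cxcl10 (-3.89 ± 0.34), Oasl1 (-3.23 ± 0.45) and Oas2 (-3.15 ± 0.27), with adjusted p = 1.8e-05, and adjusted p = 0.14 with an estimated correlation. Both lists fell here. In iTSCs against heterozygous ESCs, though, 15 interferon genes were called higher and 2 fibroblast genes lower. Fibroblast genes summed to 13071 to 13114 CPM in wild-type TSCs and 892 to 1855 CPM in iTSCs. Without wild-type TSC replicate 1, 2 or 3, 7 fibroblast genes fell, and without iTSC replicate 3 or 4, 6 fell. Genes of the 2-cell-like state were called higher in 22 of 33 cases and lower in 1 (23 and 1 adjusted over the list alone), with adjusted p = 1.6e-12, and adjusted p = 0.14 with an estimated correlation; Zscan4d had 195 counts over the iTSC libraries. Eif2s3y (-4.94 ± 0.67) and Ddx3y (-4.37 ± 0.73) fell. edgeR called 5951 genes, 3323 higher and 2628 lower, and the share called higher of 55.8% became 34.8% with limma on log2(FPKM + 1). The 2 groups fitted alone gave 9803 genes, and leaving out wild-type TSC replicate 1, 2 or 3 gave 3813, 3846 or 3854; library series and genotype cannot be told apart here.

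Heterozygous and wild-type ESCs were compared for the effect of the Rif1 genotype, as labelled. Heterozygous replicate 1 was kept under its label, although it had 41.6 CPM of Rif1. An exchange of its label with the library labelled homozygous stays open. Pou5f1 (-0.39 ± 0.27, adjusted p = 0.30) and Nanog (0.42 ± 0.33, adjusted p = 0.37) did not pass the test, although Pou5f1 was called at -0.69 (adjusted p = 0.039) without heterozygous replicate 1 and at -0.87 (adjusted p = 0.0029) with a length and GC correction, and Nanog at 0.55 (adjusted p = 0.011) with limma on log2(FPKM + 1). Rif1 fell by 1.69 ± 0.52 (adjusted p = 0.030), a call that was lost without any 1 of the wild-type replicates (-1.68 to -1.69, adjusted p = 0.068 to 0.070) or without heterozygous replicate 3 (-1.56, adjusted p = 0.070), without a low-count filter (-1.64, adjusted p = 0.066) and with the 2 groups fitted alone (-1.68, adjusted p = 0.13). With the library labelled homozygous added to the heterozygous ones Rif1 was at -0.29 (adjusted p = 0.85), and its adjusted p over 18 alternatives started at 0.00069. Hmgn3 rose by 2.17 ± 0.35 (adjusted p = 0.0011). Cdx2 (-3.34 ± 0.33) and Eomes (-1.84 ± 0.21) fell, Cdx2 without a call on log2(FPKM + 1) (-0.50, adjusted p = 0.064), and Elf5 had 25 counts against 3, a ratio of 7.58 with an interval of 2.59 to 36.7. Eif2s3y, Ddx3y, Tex13b and Stra8 rose by 8.97 ± 0.86, 6.63 ± 0.85, 6.73 ± 0.91 and 6.47 ± 1.01. Itga11, a collagen receptor, was called higher by 6.01 ± 1.56, and lost its call without heterozygous replicate 3 (1.73, adjusted p = 0.054) and without wild-type replicate 1 (5.60, adjusted p = 0.063) or 3 (5.79, adjusted p = 0.065). Trh (-5.50 ± 1.08), Spink1 (-5.07 ± 0.52), Nt5e (-4.77 ± 0.72), Trpm1 (-4.12 ± 0.41) and Soga3 (-4.03 ± 0.90) fell.

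Germline genes that DNA methylation silences rose in 21 of 23 cases (23 adjusted over the list alone), including Dazl (4.43 ± 0.49), Tuba3a (4.03 ± 0.39), Mov10l1 (3.98 ± 0.40) and Rhox5 (3.62 ± 0.32), with adjusted p = 1.0e-16, and adjusted p = 0.11 with an estimated correlation. DNA methylation genes fell in 6 of 9 cases (6 lower and 1 higher adjusted over the list alone), including Dnmt3l (-1.83 ± 0.25), the methyltransferase Dnmt3b (-1.67 ± 0.17), the dioxygenase Tet2 (-1.67 ± 0.38) and Uhrf1 (-0.51 ± 0.13), with adjusted p = 0.0010, and adjusted p = 0.19 with an estimated correlation. H3K9 silencing genes fell in 7 of 14 cases (9 lower and 1 higher adjusted over the list alone), including Setdb1 (-0.95 ± 0.15), Cbx5 (-1.17 ± 0.20), Cbx1 (-0.84 ± 0.18) and Atrx (-1.83 ± 0.50), with adjusted p = 0.0012, and adjusted p = 0.19 with an estimated correlation; 4 fell without wild-type replicate 1, 2 or 3. With the 2 groups fitted alone, Tet2 (-1.67, adjusted p = 0.065), Uhrf1 (-0.52, adjusted p = 0.079), Cbx1 (-0.84, adjusted p = 0.067) and Atrx (-1.83, adjusted p = 0.087) lost their calls, as did Uhrf1 with limma on unfiltered FPKM (-0.37, adjusted p = 0.054). With the library labelled homozygous added, calls were lost for Dnmt3l (-1.23, adjusted p = 0.053), Dnmt3b (-0.94, adjusted p = 0.14), Tet2 (-1.14, adjusted p = 0.11), Cbx5 (-0.60, adjusted p = 0.30), Cbx1 (-0.66, adjusted p = 0.056) and Atrx (-1.17, adjusted p = 0.18). Pluripotency genes fell in 10 of 25 cases and rose in 1 (10 and 1 adjusted over the list alone), including Lin28a (-2.09 ± 0.13), Tfcp2l1 (-1.81 ± 0.19), L1td1 (-1.81 ± 0.27) and Tbx3 (-1.09 ± 0.16), with adjusted p = 0.00044, and adjusted p = 0.13 with an estimated correlation. Primitive endoderm genes rose in 12 of 21 cases and fell in 2 (12 and 2 adjusted over the list alone), including Gata6 (4.26 ± 0.51), Dab2 (4.01 ± 0.29), Col4a2 (2.96 ± 0.37) and Gata4 (2.34 ± 0.29), with adjusted p = 0.00092, and adjusted p = 0.085 with an estimated correlation. Fibroblast genes rose in 7 of 22 cases (7 adjusted over the list alone), with adjusted p = 0.29 for the list, and 7524 CPM of the fibroblast sum lay in heterozygous replicate 3 against 730 and 1244 CPM in the others. Without heterozygous replicate 3 the list turned, with 1 gene higher and 11 lower (adjusted p = 0.00044). It had 16 and 19 genes higher without replicates 1 and 2 (adjusted p = 0.028 and 0.016), and 2, 1 and 2 without wild-type replicates 1, 2 and 3.

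edgeR called 6638 genes between these ESCs, 4204 higher and 2434 lower in heterozygous cells. The count was 2956 with the 2 groups fitted alone, 3613 with the library labelled homozygous added to the heterozygous ones, and 4239, 4257 or 4317 without wild-type ESC replicate 1, 2 or 3. Library series and genotype cannot be told apart in this comparison.

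The library labelled homozygous was set against the heterozygous ESCs. It is a lone library assumed to vary like the other groups, and its Rif1 level goes against its label, so no direction below can be read as that of the genotype. Rif1 was 2.92 ± 0.65 higher in it (adjusted p = 0.0082). Eomes was lower by log2 fold change -2.36 ± 0.35, Pou5f1 by -1.25 ± 0.41 (adjusted p = 0.043) and Nanog had -1.47 ± 0.51 (adjusted p = 0.053), or 0.0056 with DESeq2, 0.036 without heterozygous replicate 1 (-1.50) and 0.048 without replicate 3 (-1.43); with a length and GC correction Pou5f1 was at -0.15 (adjusted p = 0.71). Enpp2, Gvin1 and Adam1a stood 8.43 ± 1.04, 7.12 ± 1.23 and 6.86 ± 0.81 higher, and Xlr4a, Spic and Crxos at -8.21 ± 0.85, -8.02 ± 0.74 and -7.79 ± 0.97. Interferon-response genes were higher in 13 of 20 cases (13 adjusted over the list alone), including Stat1 (2.29 ± 0.31), Cxcl10 (3.79 ± 0.40), Mx2 (5.01 ± 0.60) and Ddx58 (3.31 ± 0.80), with adjusted p = 3.5e-05, and adjusted p = 0.46 with an estimated correlation. Glycolysis genes were lower in 11 of 18 cases (13 adjusted over the list alone), including Hk1 (-2.87 ± 0.33), Pfkm (-1.79 ± 0.37), Aldoa (-1.71 ± 0.39) and Ldha (-1.34 ± 0.19), with adjusted p = 3.5e-05, and adjusted p = 0.46 with an estimated correlation. Fibroblast genes summed to 6376 CPM in this library. Gene length and GC content explained 31.1% of the variance of its log2 levels around the mean of all libraries, 30.3% in heterozygous replicate 1 and 3.08% to 5.87% in the others. edgeR called 5945 genes, and 65.0% of these stayed called with the length and GC correction.

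The difference between the 2 TSC-ESC comparisons was tested as (iTSC over heterozygous ESC) minus (wild-type TSC over wild-type ESC), in which a constant shift between the series cancels. Eif2s3y and Ddx3y rose in wild-type TSCs and fell in iTSCs, so differences in sex-linked genes do not cancel. Of 24 tested genes on the Y chromosome 20 were called. The fall of Pou5f1 and Nanog was smaller in the Rif1 series by 5.91 ± 0.42 and 3.41 ± 0.51. Nanog ranged from 0.67 to 4.19 over 23 alternatives and kept its call (highest adjusted p = 0.042). The rise of Cdx2 and Eomes was larger by 3.21 ± 0.42 and 1.71 ± 0.29. With limma on log2(FPKM + 1) the differences of Cdx2 and Eomes were 0.12 and 0.82 and lost their calls (adjusted p = 0.75 and 0.056). Both genes started lower in heterozygous than in wild-type ESCs, Cdx2 at 15, 8 and 8 counts. Neither passed the test between iTSCs and wild-type TSCs. Elf5, with 3 counts in wild-type ESCs, differed downward without passing the test (adjusted p = 0.060, from 0.012 to 0.80 over 23 alternatives). It passed with DESeq2 size factors (adjusted p = 0.049), DESeq2 (0.029) and the length and GC correction (0.044), and without wild-type ESC replicate 3 (0.012) or iTSC replicate 1 (0.042). Rif1 differed by 2.95 ± 0.73 (adjusted p = 0.011) and Hmgn3 by -2.90 ± 0.47 (adjusted p = 0.0012). Pluripotency genes differed upward in 17 of 25 cases and downward in 3 (18 and 3 adjusted over the list alone), including Lin28a (2.68 ± 0.19) and Tdh (5.57 ± 0.52), with adjusted p = 2.5e-15. WNT targets differed upward in 9 of 12 cases and downward in 2 (9 and 3 adjusted over the list alone), including Sp5 (7.77 ± 0.76) and Cdx1 (5.29 ± 0.54), with adjusted p = 1.1e-05. Both lists also passed with an estimated correlation. Germline genes differed downward in 15 of 23 cases (16 adjusted over the list alone), including Dazl (-7.17 ± 0.68) and Syce1 (-4.88 ± 0.50), with adjusted p = 2.9e-10, and adjusted p = 0.096 with an estimated correlation. Fibroblast genes differed downward in 21 of 22 cases (22 adjusted over the list alone), with adjusted p = 1.4e-06, and adjusted p = 0.45 with an estimated correlation; the count was 12 without any 1 of the wild-type ESC replicates and 10 without heterozygous replicate 3. edgeR called 6775 genes, 3041 upward and 3734 downward; the upward share of 44.9% became 29.8% with limma on log2(FPKM + 1).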

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

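The tests of Rif1, of ESC transcripts, of fibroblast genes and of permuted residuals below were chosen after the results were seen; the regroupings of samples were not.

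The 2 TSC-ESC comparisons differed by the test of their difference for 6775 genes and 18 gene lists. Of 60 drawn regroupings of wild-type and Rif1 libraries within ESCs and within TSCs, the real one, 1 of the 60, called the most, with 6775 genes against 1979 in the highest other. These also break up the difference between the series. With lineage and series effects kept and the residuals permuted, limma called 7482 genes in the real order, 1 of 100, and at most 2225 in the others. Such a test needs residuals that are exchangeable between groups. The spread of these groups was unequal, so it cannot exclude chance. Log2 differences were 2.95 for Rif1, -2.90 for Hmgn3, 5.91 for Pou5f1, 3.41 for Nanog, 3.21 for Cdx2 and 1.71 for Eomes. The difference was positive for Trh (10.46), Sp5 (7.77), Otx2 (6.73), Tdh (5.57), Cdx1 (5.29), Foxd3 (3.95), Notum (3.82), Lef1 (3.74), Dnmt3b (3.05) and Lin28a (2.68). It was negative for Dazl (-7.17), Mov10l1 (-4.92), Syce1 (-4.88) and Mael (-4.04). For genes with at most 3 counts in a group only the adjusted p is given, upward 8.0e-08 for Tdgf1, 2.2e-05 for Kirrel2, 9.1e-05 for Spink1 and 0.0062 for Nkx1-2, and downward 2.4e-05 for C3, 0.00043 for Dpt, 0.0031 for Lrrc17, 0.0044 for Lum and 0.016 for Lyz2. Without heterozygous replicate 3, Lyz2 and Lum were at adjusted p = 0.99992, and Lyz2 was at 0.054 without a filter. Otx2 had 0.61 (adjusted p = 0.12) with limma on log2(FPKM + 1).

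The library labelled homozygous had the highest Rif1 level and heterozygous replicate 1 the lowest, a log2 gap of 4.90. A length and GC trend as the whole cause is argued against by 200 genes matched on length, GC content and level, whose median gap was 1.59, which left 3.31, with Rif1 above 3.63, the upper end of the range that held 95% of their gaps. The matched genes had a median exon length of 8737.5 bases and GC content of 41.61%, against 10504 bases and 39.33% for Rif1. Part of what was left could therefore still follow such a trend, also in the tests of labels that follow. An exchange of the labels of these 2 libraries was tested in 2 ways that came out apart, and the second way and its limit were added only after the first had been seen. By the first, Rif1 in the library labelled homozygous exceeded wild-type ESCs by 1.23, above a limit of 1.13, the upper end of the range that held 95% of the same differences of matched genes. This left 1.07 beyond the median of those genes and taken alone would argue against the exchange, although those wild-type libraries belong to the other series. By the second, within the Rif1 series, it exceeded the higher of heterozygous replicates 2 and 3 by 1.44, under a limit of 2.50 set at 2 times the gap of 1.25 between them, so an exchange, a single wrong label and counts from an altered Rif1 allele stay open, the last 2 untested.

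ESC transcripts were present in iTSCs above wild-type TSCs. A length and GC trend as the whole cause is argued against, since 12 of the 12 pluripotency genes called higher stayed called with the correction. Residual ESCs, or reads of ESC libraries assigned to iTSCs, would need a share of at least 1.76%, the level of Pou5f1 in iTSCs against its highest ESC library. A first test asked how many of 9 abundant ESC-specific genes lay below 25% of the level that this share of the lowest ESC library gives, and 1 (11.1%) did, with a median of 1.64% of the lowest ESC library. It took the whole iTSC level as if it came from ESCs. A second test, added after the first had been seen, took as the source each of the 7 ESC libraries, with its own share for Pou5f1, and 66 mixtures of the ESC groups. Run on all protein-coding genes at 50 CPM or more in the source, it found 0.294% to 0.521% per library below 25% of the level needed. After that result it was limited to genes also under 1% of their source level in wild-type TSCs. Of 31 to 36 such genes per library, 11 to 18 lay in iTSCs below 25% of the level needed, at the upper end of their counting interval. Of 26 to 37 per mixture, 9 to 15 did, at least 28.1%. With this limit on genes, chosen after the wider run, cells like these ESCs, or their reads, are argued against as the whole cause. A smaller share for part of the genes, ESC-derived cells with another profile, and expression in iTSCs themselves stay open, untested.

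Fibroblast genes were high in wild-type TSCs. A constant shift between the series is argued against by 21 of 22 genes called higher than in wild-type ESCs of the same series. There 21 of 22 genes reached 10 CPM, led by Fn1 (3704 CPM), Col1a1 (2027), Lox (1302) and Col1a2 (1194), against 4 genes in wild-type ESCs and 10 in iTSCs. Feeder fibroblasts among the TSCs and expression by the TSCs themselves would both give such levels and cannot be told apart, and whether feeders were used is not given in the sources used here.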

How the results depend on the processing

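The length and GC correction and the fit without heterozygous replicate 1 and the library labelled homozygous were chosen after seeing the data; the other alternatives were not. The count of genes for wild-type TSCs against ESCs, the shared genes (6042 to 7950 with replicates left out) and the lineage positions (0.225 to 0.256, 0.309 to 0.373 and 0.721 to 0.745 over all alternatives) stayed within 1.5 times or 1 SD under every alternative run, taking the heterozygous SD for the library labelled homozygous, which was lowest on log2(FPKM + 1). With the compared groups fitted alone the counts were 2956 for heterozygous against wild-type ESCs, 7106 for iTSCs against heterozygous ESCs and 9803 for iTSCs against wild-type TSCs. With the homozygous-labelled library joined to the heterozygous ones the first was 3613. Wild-type TSCs against ESCs fitted alone gave 17248. Alone, counts fell where heterozygous ESCs, with the widest replicate spread, were 1 of 2 groups compared, and rose where they were not. The fit of all libraries shares 1 spread per gene between groups of unequal spread. No further cause was tested.

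With a replicate block in addition, counts were 16060 for wild-type TSCs against ESCs, 2237 and 3037 for the first pair above, 5632 for iTSCs against wild-type TSCs and 4028 for the difference of the 2 TSC-ESC comparisons. Deviations of same-numbered libraries from their group means correlated at -0.188 to 0.0129, against -0.123 to 0.139 for differently numbered ones. This gave no sign of pairing by number, but deviations around means of so few libraries cannot settle whether samples were paired.

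Leaving out 1 replicate gave 11541 to 11618 genes for wild-type TSCs against ESCs, 4239 to 7961 for heterozygous against wild-type ESCs, 9374 to 11489 for iTSCs against heterozygous ESCs, 3813 to 4459 for iTSCs against wild-type TSCs, 5134 to 8708 for the difference of the 2 TSC-ESC comparisons and 6873 to 8015 for the library labelled homozygous. Rif1 in iTSCs against heterozygous ESCs reversed to 1.00 without heterozygous replicate 2, the highest of a range from -0.50 with replicates left out. With an estimated correlation, lists called went from 21 to 6, 11 to 0, 14 to 5, 19 to 4 and 18 to 5 in the order above, the difference of the 2 TSC-ESC comparisons last.

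DESeq2 size factors moved the median of all genes by 0.12 for wild-type TSCs against ESCs, -0.10 for iTSCs against wild-type TSCs and -0.13 for the difference; log2(FPKM + 1) moved it by 0.29, -0.23 and -0.28. The share called higher went from 55.8% to 43.0% without a filter and to 34.8%, 35.1% and 28.9% with limma on FPKM for iTSCs against wild-type TSCs, and from 44.9% to 32.2%, 29.8%, 27.5% and 24.6% for the difference. It went from 50.2% to 62.3% for wild-type TSCs against ESCs with limma on unfiltered FPKM, and from 43.5% to 54.0% for the library labelled homozygous with the length and GC correction. The length and GC correction gave 13954, 7959, 11779, 7199, 7963 and 5551 genes in the order of the replicate counts. The fit without the 2 libraries gave 7763, 11478 and 8719 for the comparisons with heterozygous ESCs. Of named-gene values, 0, 44, 5, 7, 10 and 1 lost the call and 0, 5, 2, 8, 5 and 3 gained it, in the order of the replicate counts. In comparisons of 3 against 3 libraries, 10 splits cannot give a share under 0.05; the real value and the highest other were 13166 and 0, 6638 and 1, 10831 and 3, and 5951 and 0. Depth limits genes near the floor, where Elf5 in heterozygous against wild-type ESCs lost its call in 10 alternatives.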

Other observations

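The lists below were fixed earlier; which of them to describe, the levels of Dusp6 and Spry4, and the levels per library of sex-linked genes, were chosen after the results were seen. FGF and ERK targets stood higher in 4 of 13 cases and lower in 1 in the library labelled homozygous than in heterozygous ESCs (7 and 1 adjusted over the list alone), including the phosphatases Dusp4 (3.79 ± 0.30) and Dusp6 (3.32 ± 0.72), Egr1 (2.53 ± 0.33) and the inhibitor Spry4 (3.41 ± 0.91), with adjusted p = 0.00028, and adjusted p = 0.46 with an estimated correlation. This is a lone library assumed to vary like the other groups, and heterozygous ESCs had 7.77 ± 8.02 CPM of Dusp6 and 3.99 ± 5.27 of Spry4 (SD, n = 3), below 32.6 and 45.9 CPM in wild-type ESCs. Formative epiblast genes stood higher in 7 of 12 cases (7 adjusted over the list alone, and 1 lower), including Dnmt3b (1.86 ± 0.21), Lef1 (2.56 ± 0.39), Zic2 (1.90 ± 0.41) and Fgf5 (4.71 ± 1.18), with adjusted p = 0.00076, and adjusted p = 0.11 with an estimated correlation. Dnmt3b was called lower in heterozygous than in wild-type ESCs, so its difference here starts from a low level. Fibroblast genes also moved upward as a list in this library (adjusted p = 0.019, and 0.85 with an estimated correlation), with no member called. Length and GC content explained 31.1% of its variance and 30.3% in heterozygous replicate 1. Rif1 goes against the label of the library labelled homozygous.

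Replication-dependent histone genes fell in 9 of 17 cases in iTSCs against wild-type TSCs (11 adjusted over the list alone), with adjusted p = 0.00010, and adjusted p = 0.14 with an estimated correlation. Histone copies are near-identical and their mature mRNAs lack a poly-A tail, so poly-A libraries measure them poorly and their values are uncertain. Sex-linked genes rose in 5 of 7 cases in heterozygous against wild-type ESCs (5 higher and 1 lower adjusted over the list alone), with adjusted p = 0.0010, and adjusted p = 0.32 with an estimated correlation. Mean Ddx3y was 0.196 CPM in wild-type ESCs, 51.6 in wild-type TSCs, 19.2 in heterozygous ESCs, 11.2 in the library labelled homozygous and 2.49 in iTSCs. Mean Xist was 10.5 CPM in wild-type ESCs, 141 in wild-type TSCs, 78.6 in the library labelled homozygous and 1354 in iTSCs, with the limit of its overlap with Tsix. Heterozygous replicates 1, 2 and 3 had 1.20, 4.97 and 33.4 CPM of Xist and 5.26, 24.6 and 27.7 CPM of Ddx3y.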
